A study of Salmo salar with 30 samples.

How the data were processed

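Gene expression was measured in the distal intestine of Atlantic salmon with 1-colour Agilent microarrays, 1 array per fish, in 6 diets with 5 fish each (30 arrays). Per the labels, total RNA was extracted with a column kit, amplified and labelled with Cy3. Per the file headers, the arrays were quantified with Agilent Feature Extraction 12.0.1.1 under its 1-colour gene expression protocol. The deposited scanner files give each spot's processed signal as an intensity on a linear scale, background-subtracted within the array and not normalized between arrays. The other columns used, per the file headers, are flags of Feature Extraction that mark spots as well above background, saturated or non-uniform. The authors also deposited a value table of intensity values for the same arrays. Set against the scanner files, each of its columns was the spot median minus the local background median, multiplied by 1 factor per array (0.522 to 0.764) and rounded to whole numbers. The share of values within 1 unit of that product was lowest, at 98.1%, for control fish 5. The factors brought the columns to nearly equal sums of 19861896 to 19874825, with column medians of 73 to 101, and 14191 cells were blank. The values are linear, not centred, and have no direction of comparison. That table served as an alternative only.

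The array holds 14841 non-control probes. Probe identifiers are not paired with genes in the files, and 0 of the 14841 identifiers matched the reference table of gene symbols given for the species. Gene names, the rule for naming genes and the 25 gene lists fixed before the data were examined could therefore not be used, since 0 list members were found. Probes are reported by identifier, with at most 2 higher and 2 lower per main comparison. These are the probes past the threshold with the highest and lowest log2 fold changes among those well above background on all 5 arrays of both diets. This rule replaced the planned one after the data had been seen.

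The log2 of the processed signal was taken, and each array's 75th percentile over the non-control probes was subtracted, so a value of 0 is the 75th percentile of that array. Spots that Feature Extraction marked as outliers (598 over all arrays) were treated as missing, and 0 spots were saturated. Probes were kept if they were well above background on at least 5 of the 30 arrays, whatever the diet. This kept 13577 probes and left out 1264. Folds in the text are powers of 2 of the log2 difference, and a dim probe's fold depends on the background correction. Where a probe was not well above background on any array of a diet, its fold is a lower bound, written "at least". The bound sets the brighter diet's mean against a mean of, per array, the lowest signal well above background or the probe's own signal, whichever was higher.

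Differences between diets were tested with limma 3.58.1 in R 4.3.3. One linear model was fitted to all 30 arrays with 1 coefficient per diet, so that the diets shared 1 estimate of the spread, and moderated statistics were taken from eBayes without trend. The Benjamini-Hochberg adjustment was made within each comparison, and a probe passed at an adjusted p below 0.05 with no minimum fold. All adjusted p-values of single probes are from this fit. There were 5 main comparisons (each plant protein against control, and each package against its own plant protein) and 6 secondary ones. One of the latter was the difference of the P2 effect between both plant proteins. The labels name separate fish, so n counts fish. Per the labels the fish were held in 18 tanks, but the tank of each fish is not given. The p-values treat fish as independent and are too small if fish of 1 tank resembled each other.

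The change caused by a package was set against the soybean meal change in 2 ways that use different fish on each side. In the first, planned before the data were examined, each of the 10 choices of 3 soybean meal fish gave the probes past the threshold against control. The package fish were then compared with the remaining 2 soybean meal fish over those probes. In the second, added after the data had been seen, a soybean meal response score was computed per fish. Each of the 100 combinations of 3 control and 3 soybean meal fish gave a set of probes past the threshold (1302 to 3966 probes). A fish's score was the mean log2 value over that set, with the sign turned for probes that were lower with soybean meal. Only fish left out of the choice of probes were scored. Scores were averaged over combinations and set to a mean of 0 in control fish. Diets were compared on the score with exact two-sided permutation tests over the 252 arrangements of 5 fish against 5. The Benjamini-Hochberg adjustment covered the 8 tests of that family, and the smallest p these tests can give is 0.00794.

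Comparisons that share control fish resemble each other by chance. For these, correlations and covariances were also computed on 20 simulated sets of unchanged diets, and again with the 5 control fish split between both comparisons (20 splits). The overlap of independent lists was taken from the number of calls of each. The scripts were tested on simulated data built from the means and spreads of the 13577 real probes, with 200 probes changed in 1 diet. In the simulation of corn gluten + P2 against corn gluten, 20 of 67 probes changed by 0.5 log2 units passed the threshold. Of the 67 changed by 1 unit 42 passed, as did 64 of the 66 changed by 2 units. For soybean meal + P2 against soybean meal the corresponding numbers were 21 of 67, 36 of 67 and 60 of 66. A separate simulation changed probes in the soybean meal diets together, not in 1 diet. There, a retained share of 50% set for soybean meal + P2 was estimated at 50.1% by the response score. For soybean meal + P1 the estimate was 99.95%. Whether slide or tank differences would shift such estimates was not tested.

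Signal per array limits the precision as follows. The 75th percentile of the processed signal ranged from 551 to 948 intensity units between arrays, and 12491 to 13376 probes per array were well above background. Precision is further limited by the number of arrays, 5 per diet. Per the file headers, the arrays lay on 6 slides. Slides held 2 to 4 diets each, but soybean meal and control shared no slide, nor did corn gluten and corn gluten + P2. Slide was tested as a batch, as a fixed block in the model and by comparing diets within each slide that held both.

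Alternatives fixed before the data were examined were a normexp background correction (offset 50), quantile normalization, scaling to the array median, the authors' value table, 2 other filters on dim probes, eBayes with trend, array weights, a fit to only the diets compared, fish number as a block, slide as a block, presumed tank as a random block, a fold rule in place of the adjusted p, and leaving out each fish in turn. The scanner files used here hold no mean signal, so normexp was run on median signals. Presumed tanks were fish of 1 diet with adjacent numbers in the deposited names. They gave 18 presumed tanks and a consensus correlation of 0.042 between fish of 1 presumed tank. Added after the data had been seen were keeping the outlier spots, the response score with its alternatives, and the means within slides.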

Results

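Expression was profiled in the distal intestine, the hindmost gut segment, of Atlantic salmon fed 6 diets, with 5 fish per diet and 1 array per fish. The fish weighed 177 g at the start and were fed for 67 days at 11.2 °C. The control feed was rich in fish meal. Of the other feeds, 3 contained soybean meal, a plant protein known to inflame the distal intestine of salmon, and 2 contained corn gluten, another plant protein. The names of the deposited files also mention pea for these 2 feeds, which the labels do not, so whether they held pea as well is open. Soybean meal was given alone, with package 1 (P1, 0.01% butyrate and 1.5% arginine) or with package 2 (P2, nucleotides at 0.05%, β-glucan at 0.1% and butyrate at 0.01%). Corn gluten was given alone or with P2. The questions the design addresses are what each plant protein changed against control and what each package changed within its plant protein. Of 14841 probes, 13577 were kept, and 12491 to 13376 probes per array were well above background. Fish of 1 diet correlated at 0.962 to 0.987 across probes.

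Diet changed many probes, and slide beside it did not pass at any. In limma, 5377 probes differed between the 6 diets and 3731 did so with slide in the model, while 0 probes differed between slides beside diet. The comparisons fell into 2 classes. Those that set a soybean meal diet against a diet without it gave 2319 or more probes past the threshold, and all others gave 168 or fewer.

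**Figure D1:**
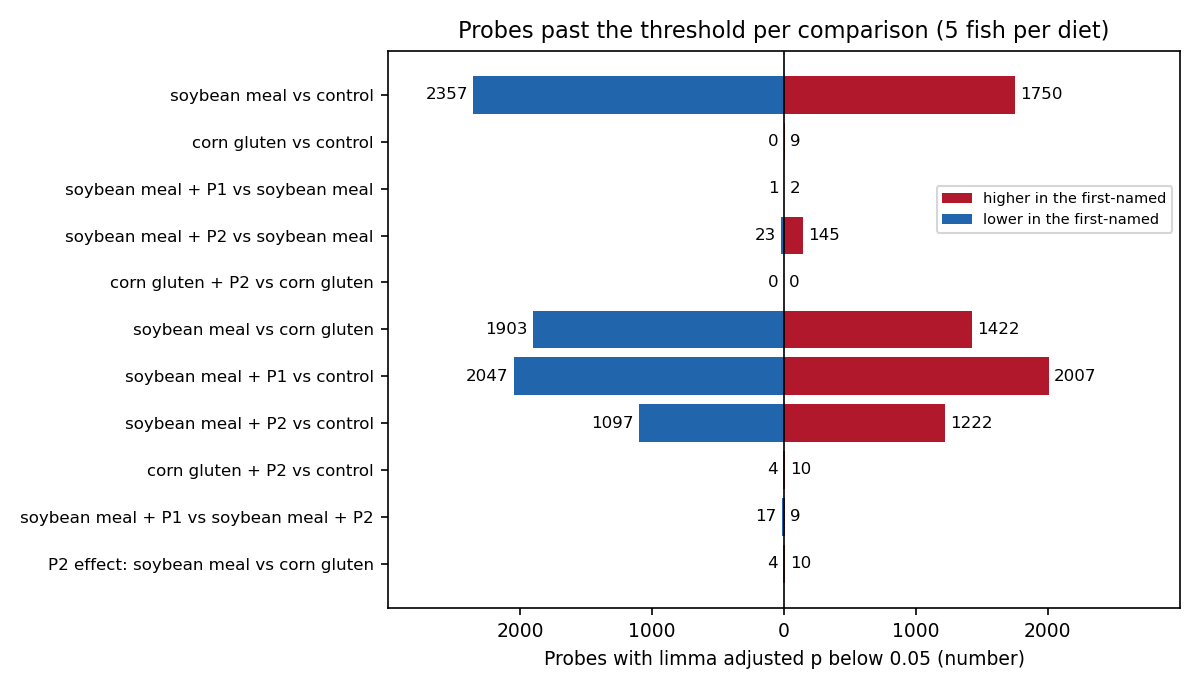
Number of probes with a limma adjusted p below 0.05 in each comparison, 5 fish per diet. Bars to the right count probes higher in the first-named diet and bars to the left those lower, and the 1750 higher and 2357 lower probes of soybean meal against control form the longest pair of bars.

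Soybean meal changed the distal intestine widely. Against control, 4107 probes (30.3% of the 13576 tested) passed the threshold, 1750 higher and 2357 lower with soybean meal. Of these, 424 were more than 2-fold higher and 779 more than 2-fold lower, and 23 and 37 differed more than 8-fold. The median size of the change among the 4107 probes was 0.70 log2 units. The probe Ssa#S47729315 rose about 120-fold, from −4.39 ± 0.30 in control to 2.52 ± 0.47 with soybean meal (log2 signal relative to the array's 75th percentile, SD, n = 5 each). The difference was 6.91 ± 0.44 log2 units (SE, adjusted p = 8.84e-11). Ssa#GRASP223647763 rose about 23.4-fold, by 4.55 ± 0.45 log2 units (SE, adjusted p = 2.03e-07). The probe Ssa#S30235658 fell about 145-fold, from 2.35 ± 0.81 to −4.83 ± 0.38 (SD, n = 5 each), a difference of −7.18 ± 0.51 (SE, adjusted p = 7.23e-10). Ssa#S18862026 fell about 42.6-fold, with a difference of −5.41 ± 0.77 (SE, adjusted p = 1.13e-05). The 4 differences were smaller with the normexp background correction, at 5.14, 3.19, −5.29 and −4.92 in this order, and all passed.

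The balance of higher and lower probes depended on the scaling of the arrays. The share of higher probes was 42.6% here, 50.3% after quantile normalization and 58.4% in the authors' value table. Soybean meal and control shared no slide. With slide as a block 2549 probes passed, and all 4107 kept their direction at a median of 0.74 log2 units, while their median SE rose from 0.164 to 0.216. With the normexp background correction 2227 probes passed.

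Corn gluten changed little in comparison. Against control 9 probes passed the threshold and all 9 were higher with corn gluten. Ssa#TC110129 rose from −4.55 ± 1.22 in control to −0.09 ± 0.57 (SD, n = 5 each), by 4.46 ± 0.54 log2 units (SE, adjusted p = 8.47e-05), and by 2.64 with the normexp background correction. Ssa#S35491585 rose about 13.9-fold, by 3.80 ± 0.60 (SE, adjusted p = 0.00211), and by 1.73 with the normexp background correction, where it did not pass. In corn gluten + P2 fish all 9 probes were also higher than in control, and 6 of them passed the threshold there. Both diets were set against the same control fish. The limma fit called 822 probes at an unadjusted p below 0.05. With slide as a block 3 probes passed, 5 did with the normexp background correction, and a fit to only the 2 diets called 0. Within the 1 slide that held both diets (2 corn gluten fish, 1 control fish), all 9 probes were higher with corn gluten, by a median of 2.03 log2 units against 1.96 over all fish. The 9 probes had been picked with these fish included, which raises such agreement.

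Of the 9 probes that rose with corn gluten, 6 were lower with soybean meal than with control, 1 was higher and 2 did not pass the threshold. Of the 6, Ssa#S19103821 was not well above background in any control or soybean meal fish, so that its difference there compares 2 diets in which it was not detected. Ssa#TC110129 was not well above background in any of the 5 soybean meal fish. It was at least 6.68-fold lower there than in control (adjusted p = 4.59e-06). Ssa#S35491585 was lower by −2.40 ± 0.60 log2 units (SE, adjusted p = 0.00339) and was well above background in 2 of the 5 soybean meal fish. Independent lists of these lengths would hold 1.56 probes with opposite directions, and with the control fish split between both comparisons an average of 3.05 were opposite. Probes of the list can vary together across fish, so they are not 9 separate observations. Both Ssa#TC110129 and Ssa#S35491585, for example, were lowest in corn gluten fish 2 and highest in fish 5 of that diet. Over all probes the log2 fold changes of both plant proteins against control correlated at 0.358 across probes with a covariance of 0.087, where simulated unchanged diets gave 0.499 and 0.055. With the control fish split the values were 0.132 and 0.037. Compared directly, soybean meal and corn gluten differed at 3325 probes, 1422 higher and 1903 lower with soybean meal. The share of higher probes was 42.8%, against 54.4% in the authors' value table. With slide as a block 1825 probes passed, and on the 1 slide that held both diets (1 soybean meal fish, 3 corn gluten fish) 3305 of the 3325 had the direction seen over all fish. The 3325 probes had been picked with these fish included, which raises such agreement.

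**Figure D2:**
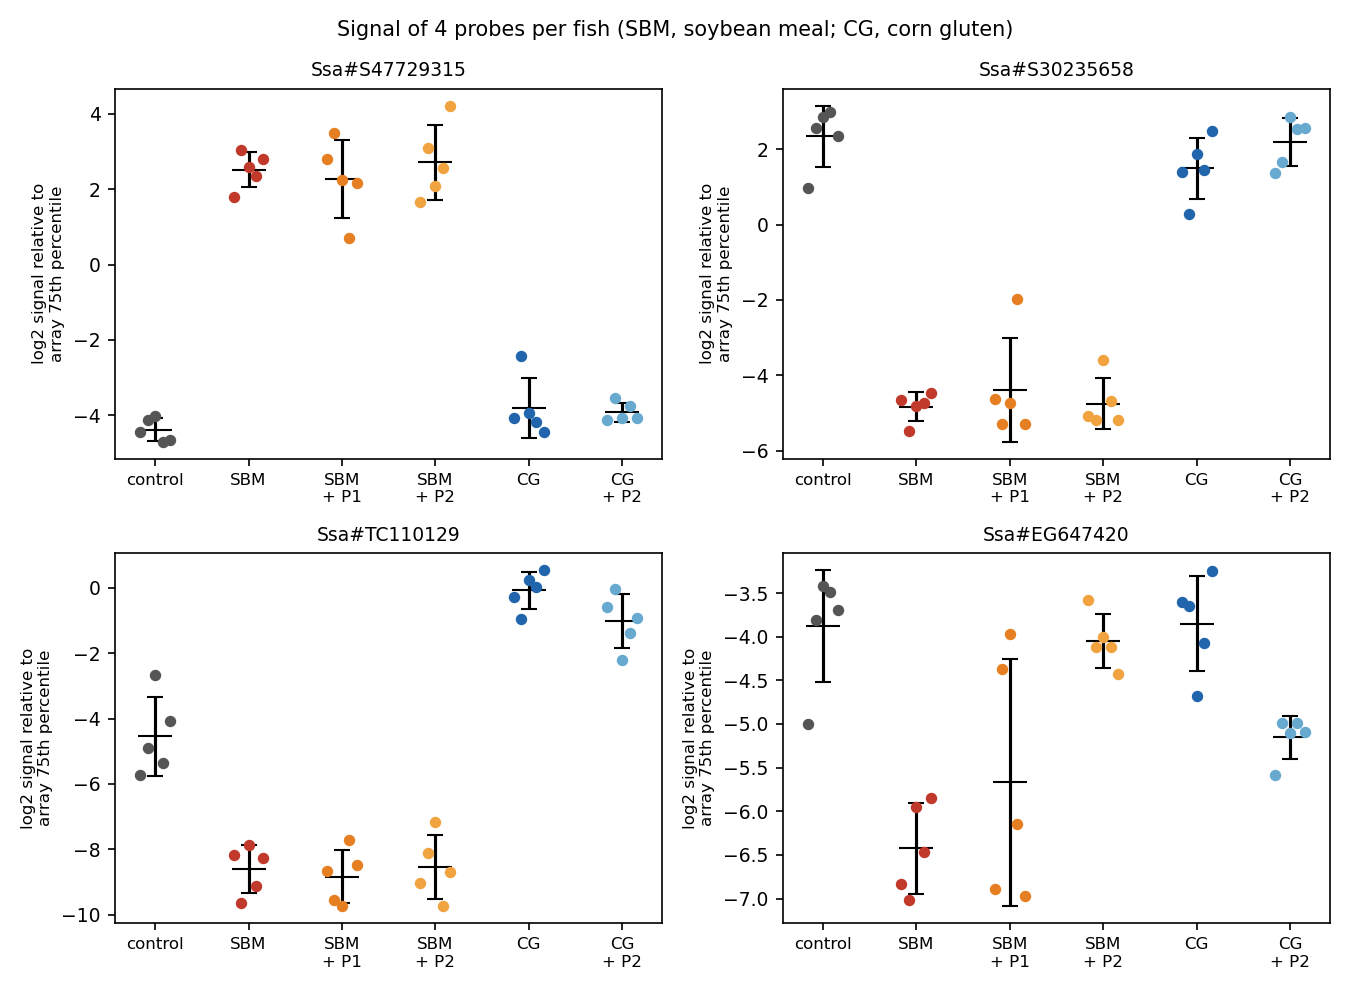
Log2 signal relative to the array's 75th percentile (vertical axis) of 4 probes in the 6 diets. Points are fish, horizontal bars the mean and error bars the SD (n = 5). Ssa#S47729315 and Ssa#S30235658 stayed at the soybean meal level with both packages, Ssa#TC110129 was highest with corn gluten, and Ssa#EG647420 with soybean meal + P2 lay at −4.05, near its control level.

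Adding P1 to soybean meal changed 3 probes, 2 higher and 1 lower. Ssa#S35523722 rose by 0.92 ± 0.15 log2 units and Ssa#DW181704 by 0.82 ± 0.13 (SE, both adjusted p = 0.0101). Both also rose with P2, by 0.97 ± 0.15 and 0.74 ± 0.13 (SE, adjusted p = 0.00495 and 0.00959). With slide as a block 1 probe passed as higher with P2, and 1 did with the normexp background correction. At least 1 of these 2 P2 calls was therefore lost in each setting. The comparisons of P1 and of P2 with soybean meal share their soybean meal fish. Ssa#S31999895 fell about 6.27-fold with P1, with a difference of −2.65 ± 0.44 (SE, adjusted p = 0.0101), from −1.30 ± 0.55 with soybean meal alone to −3.95 ± 1.46 (SD, n = 5 each). With P2 it did not pass, at −0.52 ± 0.44 (SE, adjusted p = 0.49). The difference between both packages at this probe passed the threshold, at −2.13 ± 0.44 (SE, adjusted p = 0.0434). This call was lost with slide as a block and in a fit to only the 2 package diets, where 0 probes passed. The count of 3 rested on few fish. It was 0 without soybean meal fish 5, and 18, 6 and 27 without soybean meal fish 2, 3 and 4, and 5 without soybean meal + P1 fish 5. Of the 18 and the 27, 14 and 24 were lower with P1, and the 2 called with the normexp background correction were both lower. A fit to only the 2 diets called 0. With the normexp background correction Ssa#S35523722 had 0.20 and Ssa#DW181704 0.34, and neither passed, while Ssa#S31999895 passed at −1.80. In the authors' value table Ssa#DW181704 had 0.68 and did not pass. Ssa#S31999895 also did not pass without soybean meal fish 1 (−2.53). In soybean meal + P1 fish 3 and 4, which shared a slide and a presumed tank, this probe lay at −5.68 and −5.39. In the other fish of that diet it lay between −3.10 and −2.62.

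Adding P2 to soybean meal changed 168 probes, 145 higher and 23 lower with P2. The share of higher probes was 86.3%, against 66.7% in the authors' value table (12 higher, 6 lower) and 63.6% of the 198 called in a fit to only the 2 diets. Of the 168, 143 also passed the threshold between soybean meal and control, and all 143 had the opposite sign there. Both comparisons contain the same 5 soybean meal fish with opposite signs, which favours opposite signs in advance, so this count is no test. The 143 were 124 probes lower with soybean meal that rose with P2 and 19 higher with soybean meal that fell. Ssa#EG647420 rose by 2.37 ± 0.44 log2 units with P2 (SE, adjusted p = 0.0169), from −6.42 ± 0.52 to −4.05 ± 0.31 (SD, n = 5 each). It had been lower with soybean meal than with control by −2.54 ± 0.44 (SE, adjusted p = 0.000107). Ssa#S35585574 rose by 2.62 ± 0.65 (SE, adjusted p = 0.0443). Ssa#DY732310 and Ssa#CA037592 fell, with differences of −2.25 ± 0.51 and −1.64 ± 0.30 (SE, adjusted p = 0.037 and 0.0169). With the normexp background correction Ssa#EG647420 had 0.36, Ssa#S35585574 1.53 and Ssa#DY732310 −0.92, and with slide as a block 1.85, 1.78 and −1.89, and none of these passed. Ssa#EG647420 also did not pass without soybean meal fish 1 (2.27) or soybean meal + P2 fish 1 (2.25), nor Ssa#CA037592 without soybean meal fish 1 (−1.56). Ssa#S35585574 passed only without soybean meal fish 5 (2.73) or soybean meal + P2 fish 5 (3.23) when 1 fish was left out, and Ssa#DY732310 only without soybean meal fish 2 or 5 (−2.32 and −2.15) or soybean meal + P2 fish 5 (−2.65). In the authors' value table Ssa#S35585574 (2.40) and Ssa#DY732310 (−1.91) did not pass. Ssa#S35585574 also did not pass without the filter, with fish number or presumed tank as a block, or in a fit to only the 2 diets, where Ssa#CA037592 did not pass either.

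The number of probes called for P2 was unstable. It was 3, 256, 59 and 92 without soybean meal fish 1, 2, 3 and 4, and 9, 102, 36, 11 and 459 without soybean meal + P2 fish 1, 2, 3, 4 and 5. It was 2 with the normexp background correction, 18 in the authors' value table and 2 with slide as a block. All 168 kept their direction with slide as a block, at a median of 0.79 against 0.88 log2 units, and their median SE rose from 0.197 to 0.249. On the slide that held both diets (2 fish with P2, 1 without), all 168 had the direction seen over all fish, with a median of 0.77. The 168 probes had been picked on all 10 fish, which raises such agreement.

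The sizes of both package effects were therefore set against the soybean meal change with different soybean meal fish on each side. Over the probes that passed between 3 soybean meal fish and control (2560 to 3926 probes), the P2 change against the remaining 2 fish correlated negatively with the soybean meal change. The mean r across probes was −0.629, with a range of −0.758 to −0.486 over the 10 choices of fish. On average 76.8% of these probes had opposite signs. For P1 the mean r was −0.256 with a range of −0.558 to 0.028, so its sign depended on which fish were chosen, and 55.5% of probes had opposite signs. Probes are not independent replicates, and these correlations carry no p-value. In most choices, soybean meal fish of 1 slide and 1 presumed tank stood on both sides. What such fish share enters with opposite signs and still favours a negative r.

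The soybean meal response score was computed per fish. It was 0.878 ± 0.125 with soybean meal, 0.814 ± 0.179 with P1 and 0.578 ± 0.131 with P2 (mean log2 units above control, SD, n = 5 each). Of the soybean meal change, P2 fish thus retained 65.8% (fish between 48.8% and 83.9%) and P1 fish 92.8% (between 58.2% and 107%). The score was lower with P2 than with soybean meal alone by a difference of −0.300 (exact permutation test, two-sided, p = 0.0159, adjusted p = 0.0423), and 4 of the 5 P2 fish lay below every soybean meal fish. With slide as a term the difference was −0.286 ± 0.105 (SE). On the slide that held both diets it was −0.354 (2 fish against 1). With the normexp background correction it was −0.123 and did not pass (exact permutation test, two-sided, p = 0.254). In the authors' value table it was −0.256 (exact permutation test, two-sided, p = 0.0159). P1 and soybean meal alone differed by −0.064, less than the spread between fish (exact permutation test, p = 0.540, adjusted p = 0.617). With slide as a term this difference was −0.100 ± 0.085 (SE). On the slides that held both diets it was −0.262 (2 fish each) and −0.001 (1 P1 fish against 2). With the normexp background correction P1 fish scored above soybean meal fish, at 0.717 against 0.659. The difference between P1 and P2 was 0.236 and did not pass (exact permutation test, p = 0.0556, adjusted p = 0.111). With slide as a term it was 0.185 ± 0.102 (SE). Both package diets stayed far above control, with all 5 fish of each above every control fish (exact permutation tests, both p = 0.00794, the smallest possible, adjusted p = 0.0318).

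**Figure D3:**
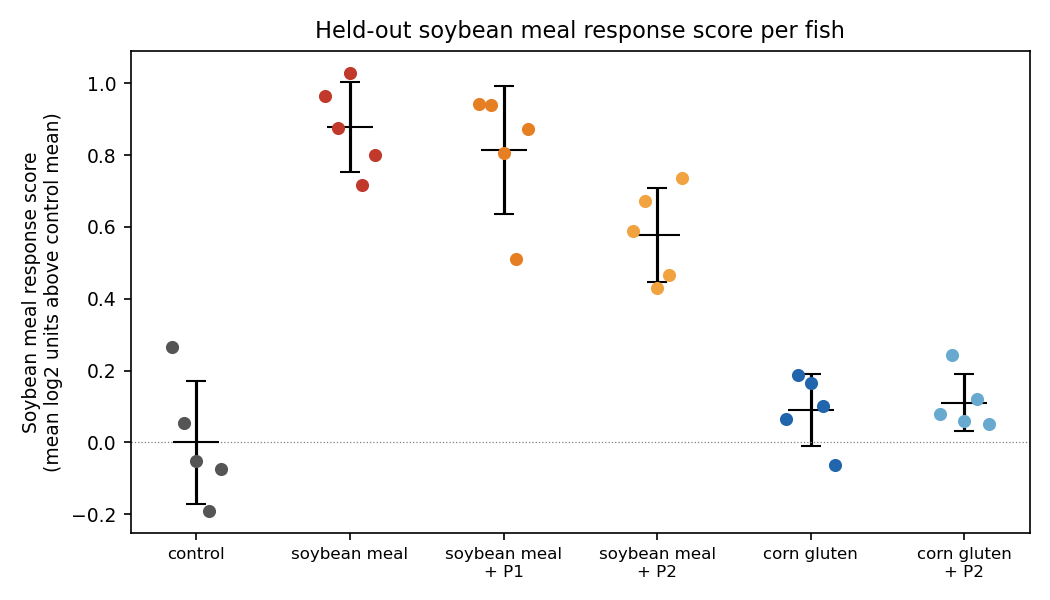
Soybean meal response score (vertical axis, mean log2 units above the control mean) of each fish, by diet. Points are fish, horizontal bars the mean and error bars the SD (n = 5). Soybean meal + P2 fish lie between 0.429 and 0.737, soybean meal fish between 0.718 and 1.03, and fish of both corn gluten diets at or below 0.244.

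Of the 4 probes named for soybean meal, none passed the threshold for either package. Ssa#S47729315 differed from soybean meal alone by 0.20 ± 0.44 log2 units with P2 and by −0.24 ± 0.44 with P1 (SE, adjusted p = 0.82 and 0.869). Ssa#S30235658 differed by 0.08 ± 0.51 with P2 and 0.45 ± 0.51 with P1 (SE, adjusted p = 0.944 and 0.772). Ssa#GRASP223647763 had a difference of −1.70 ± 0.45 with P2 and −0.58 ± 0.45 with P1 (SE, adjusted p = 0.0536 and 0.649). Ssa#S18862026 had 1.82 ± 0.77 with P2 and −1.54 ± 0.77 with P1 (SE, adjusted p = 0.169 and 0.488). Against control, 4054 probes passed with soybean meal + P1 (2007 higher, 2047 lower) and 2319 with soybean meal + P2 (1222 higher, 1097 lower). Scaling to the array median moved the share of higher probes from 49.5% to 61.9% with P1 and from 52.7% to 65.7% with P2. The packages compared directly differed at 26 probes, 9 higher and 17 lower with P1, and this count was 0 with slide as a block. It was 6, 9, 2, 321 and 4 without soybean meal + P1 fish 1, 2, 3, 4 and 5, and 4, 13, 4 and 8 without soybean meal + P2 fish 1, 3, 4 and 5.

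Soybean meal and soybean meal + P1 shared 1350 higher and 1615 lower probes in their comparisons against control, and 2 probes went opposite ways. Independent lists of these lengths would share 259 and 355. With soybean meal + P2, 959 higher and 916 lower probes were shared and 1 went the opposite way, where independent lists would share 157.5 and 190.5. Part of such overlap comes from the shared control fish. The correlation of log2 fold changes across probes was 0.826 for P1 and 0.662 for P2, where simulated unchanged diets against the same controls gave 0.499 and 0.504. Their covariances were 0.382 and 0.244, against 0.055 in both simulations. With the control fish split between both comparisons, an average of 667 higher and 818 lower probes were shared with P1, and 370 and 404.6 with P2.

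Adding P2 to corn gluten changed 0 probes in limma. At an unadjusted p below 0.05 there were 1028 probes, and the smallest adjusted p was 0.229. Corn gluten and corn gluten + P2 shared no slide, so no value within a slide exists, and with slide as a block 0 probes passed. The response score did not differ between corn gluten with P2 (0.110 ± 0.080) and without it (0.091 ± 0.100, SD, n = 5 each) by more than the spread between fish (exact permutation test, p = 0.722, adjusted p = 0.722). Neither diet passed against control on the score (exact permutation tests, p = 0.254 and 0.333, adjusted p = 0.406 and 0.444). With slide as a term, the difference from control was 0.081 ± 0.100 with corn gluten + P2 and 0.190 ± 0.105 with corn gluten (SE). On the slides shared with control it was −0.070 for corn gluten + P2 (2 fish each) and 0.206 for corn gluten (2 fish against 1). Against control 14 probes passed with corn gluten + P2, 10 higher and 4 lower. This count was 2 with slide as a block. It was 5, 7 and 6 without control fish 1, 2 and 5, and 3, 7 and 4 without corn gluten + P2 fish 1, 2 and 5. On the slide that held both diets (2 fish each) all 14 had the direction seen over all fish, but they had been picked with these fish included. Corn gluten and corn gluten + P2 shared 6 higher probes against control, where independent lists would share 0.0066 and an average of 1 was shared with the control fish split. The correlation of log2 fold changes across probes was 0.549 with a covariance of 0.087, where simulated unchanged diets gave 0.492 and 0.054. With the control fish split it was 0.179 with a covariance of 0.036.

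The P2 effect itself differed between the plant proteins at 14 probes, 10 more positive in soybean meal and 4 more negative. The balance turned in the authors' value table, with 20 more positive and 28 more negative. At Ssa#EG647420 the difference of the P2 effects was 3.67 ± 0.62 log2 units (SE, adjusted p = 0.0365). P2 raised it by 2.37 ± 0.44 in soybean meal, while in corn gluten the P2 change was −1.30 ± 0.44 and did not pass (SE, adjusted p = 0.476). The 14 calls were fragile. In limma 2385 probes lay at an unadjusted p below 0.05, and with slide as a block 0 passed. The count was 0 without each of corn gluten fish 1, 4 and 5, corn gluten + P2 fish 2, 3 and 5, soybean meal fish 3 and soybean meal + P2 fish 1 to 4. It was 60 and 25 without corn gluten fish 2 and 3, several times higher without corn gluten + P2 fish 4, and 4, 136, 1 and 41 without soybean meal fish 1, 2, 4 and 5, and 341 without soybean meal + P2 fish 5.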

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

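The response score, its test under scaling alone and the tests on the probes that rose with corn gluten were chosen after the data had been seen.

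Of 50 groups of 5 values tested for a fish far from the others, 4 held one, where chance gives about 1 in 20. The 75th-percentile signal of soybean meal + P2 fish 1 was 606 intensity units, with the other 4 fish of that diet between 805 and 886. On the array of corn gluten + P2 fish 3, 61 spots were marked as outliers, against 0 to 15 on the others of that diet. Soybean meal + P2 fish 5 had −4.12 at Ssa#S35585574, with the other 4 fish between −1.40 and −0.32. The same fish had −4.60 (−4.595) at Ssa#DY732310, with the others between −6.73 and −6.34. The P2 effect differed between soybean meal and corn gluten at 14 probes by the test of the difference itself.

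Soybean meal + P2 fish scored lower than soybean meal fish on the soybean meal response, by a difference of −0.300. The values argue against slide as the whole cause, since with slide as a term the difference was −2.711 times its SE. The 2 diets shared 1 slide, with 2 P2 fish against 1. Every presumed tank lay wholly on 1 slide. P2 fish scored 0.43 and 0.47 on 1 slide, 0.59 and 0.67 on another and 0.74 on the last. Tank differences were not separated from P2 and stay open. Under scaling alone, by quantiles or the array median, the score difference was −3.584 times its SE or further from 0. It thus did not hinge on the choice among these scalings. The score turns the sign of probes lower with soybean meal, so a shift of a whole array largely cancels in it. These scalings could therefore hardly have changed it. Background correction cannot be told apart from an effect of P2, since with normexp the difference was −1.249 times its SE. The authors' value table, which subtracts the local background from the spot median, gave −0.256, or −3.41 times its SE. The difference was thus smaller than −0.300 with both other background treatments, and much smaller only with normexp. An effect of the P2 ingredients, which the design names, may account for the pattern and remains a hypothesis.

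Of the 9 probes higher with corn gluten than with control, 6 were lower with soybean meal, 1 was higher and 2 did not pass. The 6 had opposite signs beyond 2 SE, which low or high control fish alone would not give, but these are the values that prompted the test, and such fish as the source of 1 of both differences stay open. With slide as a block the number was also 6 of the 9, although 3 of the 9 passed between corn gluten and control there. Soybean meal and control shared no slide, and the probes had been picked on these fish, so slide differences stay open. Without Ssa#S19103821, not detected with either control or soybean meal, 5 of 8 had opposite signs, both without and with slide as a block. Opposite effects of both plant proteins on these probes may be the source, as a hypothesis from 9 probes found and tested on the same fish. Some of these probes varied together across fish, so they are not 9 separate observations.

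Regrouping the same fish in 100 splits, the real one included, tested whether chance could give as many probes. For soybean meal against control only the real split gave as many (4107 probes, highest other 2184, 1 split as large). Only the real split did so too, with 1 split as large each, for corn gluten against control (9, highest other 3) and soybean meal + P2 against soybean meal (168, highest other 83). The same holds for soybean meal against corn gluten (3325, highest other 640), soybean meal + P1 against control (4054, highest other 2791) and soybean meal + P2 against control (2319, highest other 696). A share of 1 split in 100 is the smallest these splits can give. With 11 comparisons and no adjustment over them, it does not exclude chance by itself. The splits also treat fish of 1 slide or tank as independent. With slide as a block 3 probes passed for corn gluten against control and 2 for P2 within soybean meal. For corn gluten + P2 against control 3 splits were as large (14, highest other 78). This does not exclude chance either, and with slide as a block 2 probes passed. For the difference of the P2 effects 2 splits were as large (14, highest other 250). Fish were regrouped within each plant protein, so these splits test for a P2 effect in either one, not for a difference between them. They cannot exclude chance as the source of that difference, and with slide as a block 0 probes passed. Chance cannot be excluded for soybean meal + P1 against soybean meal (3, highest other 37, 6 splits as large) or for soybean meal + P1 against soybean meal + P2 (26, with several times as many in the highest other, 5 splits as large). For corn gluten + P2 against corn gluten (0 probes in limma, 1028 at an unadjusted p below 0.05, highest other 52) all 100 splits were as large by construction, so the splits say nothing about chance there. Splits with several times the real count, such as 250 against 14, may reflect a structure among the fish or probes that vary together, and no test here tells which. Whether those splits followed slides was not examined.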

How the results depend on the processing

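Keeping the outlier spots, the response score with its alternatives and the means within slides were chosen after the data had been seen; the other alternatives were planned.

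Counts of probes that moved by over 1.5 times are given by setting, and the cause was not tested unless stated. With the normexp background correction, soybean meal against control gave 2227, corn gluten against control 5, soybean meal + P2 against soybean meal 2, soybean meal against corn gluten 1839, corn gluten + P2 against control 6, P1 against P2 7 and the difference of P2 effects 0. This correction moved the median log2 fold change of all probes to −0.14 for soybean meal against control, and to between −0.30 and 0.16 over all comparisons. The retained share was 81.3% with P2 and 108.7% with P1 there. With slide as a block the same order of comparisons gave 2549, 3, 2, 1825, 2 for corn gluten + P2 against control, 0 and 0, and soybean meal + P1 against control gave 2630. The SE rose with slide as a block, for soybean meal against control from 0.164 to 0.216 at the median.

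At an unadjusted p below 0.05 with an absolute log2 fold change above 0.8, the counts were 1976 for soybean meal and 210 for corn gluten against control, 297 for P1 and 961 for P2 within soybean meal, and 359 for P2 within corn gluten. They were 1655 for soybean meal against corn gluten, 1648, 915 and 596 for soybean meal + P1, soybean meal + P2 and corn gluten + P2 against control, 568 for P1 against P2 and 1334 for the difference of P2 effects. This rule has no adjustment. Under it corn gluten against control had 79 higher and 131 lower, and P1 within soybean meal 72 higher and 225 lower. P2 within soybean meal had 475 higher and 486 lower, and the difference of P2 effects 574 more positive and 760 more negative.

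A fit to only the diets compared, with fewer fish to estimate the spread, gave 0 for corn gluten against control, 0 for P1 within soybean meal, 1 for P2 within corn gluten, 1439 for soybean meal + P2 and 2 for corn gluten + P2 against control, 0 for P1 against P2 and 108 for the difference of P2 effects. For P2 within soybean meal, the authors' value table gave 18, eBayes with trend 258 and the presumed tank block 64. For P1 against P2, median scaling gave 13, no filter 13, array weights 308 and the presumed tank block 11. For the difference of P2 effects, the authors' value table gave 48, trend 9, the presumed tank block 0, median scaling 123, no filter 2, array weights 270, quantile normalization 211 and probes well above background on all arrays 0. In limma this difference had 2385 probes at an unadjusted p below 0.05.

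In 0 of 15 pairs of diets did every pair of fish with 1 number correlate above 0.1, so the numbers were not taken to pair the fish. The mean correlation per pair of diets ran from −0.123 to 0.206, the latter for P1 with P2. With fish number as a block, P1 against P2 gave 44 and the difference of P2 effects 63 (29 more positive, 34 more negative), and no other count moved by over 1.5 times.

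Leaving out 1 fish gave 3251 to 4524 for soybean meal and 7 to 12 for corn gluten against control, 0 to 27 for P1 and 3 to 459 for P2 within soybean meal, and 0 to 1 for P2 within corn gluten. The ranges were 2496 to 3303 for soybean meal against corn gluten, 3229 to 4267, 1677 to 2528 and 3 to 19 for soybean meal + P1, soybean meal + P2 and corn gluten + P2 against control, 2 to 321 for P1 against P2 and 0 to 341 for the difference of P2 effects.

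The correlation across probes of the package change with the soybean meal change was −0.504 for P1 and −0.761 for P2 when the same 5 soybean meal fish stood on both sides. Those fish then enter with opposite signs, which lowers it. The probes named for the main comparisons were followed under the alternatives, each in its own main comparison. Of these 296 values, 44 lost their call, 0 changed direction and the others kept it. Calls of these probes in other comparisons, such as the difference of P2 effects, were not followed in this way. Lost calls were 0 of 92 for soybean meal and 3 of 44 for corn gluten against control, and 10 of 69 for P1 and 31 of 91 for P2 within soybean meal. The shifts of the gene lists, the spread of list scores and the named genes were not run, since 0 list members were found. Dim probes are limited by signal over background, and 11484 probes were well above background on all arrays.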

Other observations

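The test of the hypothesis below used the response score, which was chosen after the data had been seen.

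Some probes past the threshold were not well above background on any array of the diet in which they were lower, whatever their detection in the other. Of the probes higher with soybean meal than with control, 26 were not well above background on any control array. Of those lower, 66 were not well above background on any soybean meal array. Against corn gluten the corresponding numbers were 23 and 44.

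At all 14 probes where the P2 effect differed between the plant proteins, the P2 change in soybean meal had the opposite sign to the soybean meal change, and the P2 change in corn gluten had the same sign. Sharing of fish and the choice of these probes favour such signs. As a hypothesis, P2 might have moved corn gluten fish towards the soybean meal profile. The response score did not bear this out, with a difference of 0.0197 ± 0.0571 (SE) between corn gluten + P2 and corn gluten (exact permutation test, two-sided, p = 0.722). With slide as a term the difference was −0.109 ± 0.117 (SE), and these 2 diets shared no slide. The score averages over all probes of the soybean meal response, so it does not test the 14 probes alone.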
